A study of Drosophila melanogaster with 3 samples.

How the data were processed

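The material was GFP-tagged CG12071 immunoprecipitated from embryos aged 12 to 24 hours in 3 biological replicates, which the labels number as separate samples of 1 group. Per the labels, chromatin was sonicated to 200 to 800 bp and the assembly was dm6. Per the sample file records, peaks and background were called on the alignments of each replicate and on the pooled alignments of all 3, each time against the same control, and the thresholded list was derived from these lists with the irreproducible discovery rate (IDR). The aligner and the peak caller were not given in the sources used here. The age field of the labels holds a value that is not an age in hours for an embryo, so the collection window was taken from the source name.

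The deposited score of a peak is the signal value that the authors' peak caller gave it, with a scale that the sources used here do not state. It was used only to rank and filter entries within 1 list. The deposited −log10 q-value of each peak, in the column the peak format assigns to it, reached a ceiling of 3.89 in the pooled list that 3923 entries shared, and was used only to count entries at a q-value of 0.05 or less. Each of the 4 lists of peaks and background ended at 30000 entries, so their lengths carry no information on binding. Most entries had 1 fixed width, 370 bp for 93.2% of the pooled list. Read totals were not used here, so differences in depth between replicates can only be seen through the number of entries at a given q-value. A replicate with fewer such entries fills more of its strongest 4261 entries with weak ones.

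Gene models came from Ensembl release 115 (BDGP6.54) and sequence from the RefSeq copy of release 6 of the genome, which share coordinates with dm6. No entry ran past the end of an arm. All entries lay on 2L, 2R, 3L, 3R, 4 and X, and transposable elements were left out of the annotation. The 19607 TSSs of all transcripts of 13945 protein-coding genes were used. A gene was called bound when a thresholded summit lay within 500 bp of any of its TSSs. Each summit was put into the first class that applied: promoter, 5' UTR, coding exon, 3' UTR, other exon, intron or intergenic.

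Classes were compared with 1000 sets of random non-N positions with the same number per arm (permutation test, two-sided), arms with a two-sided exact binomial test, and gene lists with two-sided Fisher exact tests against all other protein-coding genes. Beside each list, 10000 random lists were drawn that matched it on the number of distinct TSSs per gene. A thresholded peak was supported by a replicate when a summit among that replicate's 4261 strongest entries lay within 100 bp, and chance was set by 100 circular shifts along each arm. Motifs and 8-mers were sought on both strands within 50 bp of the summit and in a window of the same width centred 300 bp to one randomly chosen side, with two-sided exact McNemar tests on discordant peaks. Adjusted p-values are Benjamini-Hochberg within each family, with a threshold of 0.05. Intervals on shares are Wilson 95% intervals.

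Listed gene symbols that the annotation does not hold were dropped. The 26 gene lists, the motifs, the tests described above, the rule for named genes and all alternatives but those given last below were fixed before the data were examined. Further tests, given under the later headings, include some chosen after results had been seen. The named genes are the tagged gene, the genes of the 15 strongest promoter peaks and of the 5 strongest peaks farther than 500 bp from a TSS among peaks supported in all 3 replicates, and up to 4 members with the strongest supported promoter peak of each list past the threshold. The alternatives were other TSS windows (250 and 1000 bp), 1 TSS per gene, the 2130 strongest thresholded peaks and peaks supported in all 3 replicates. Further ones were other rules for shared peaks, other motif windows (25 and 100 bp) and controls, 6-mers, exchanged arms, and leaving out each replicate. For the promoter share of thresholded peaks and the gene lists, leaving out a replicate kept the thresholded peaks supported by both other replicates. These were 58.0%, 54.1% and 64.7% of peaks without replicates 1, 2 and 3. The thresholded list was made from all 3 replicates, so the one left out still shaped it. Single-replicate gene lists, the 1000 strongest entries, the promoter share without each replicate, calls from the matched draws with and without adjustment over the lists, and divergent promoters with each peak given to the nearest TSS only were added after the data had been seen.

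The computations used Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9. They were tested on simulated data with fixed seeds. In 50 simulations over 13945 genes with a background of 13% bound, ribosomal protein genes bound with a probability of 50% were called every time, fat body and metabolism genes at 40% in 84% of simulations, and chemoreceptor genes at 1% every time. Lists that held no planted effect were called in 1.16% of tests. Simulated genes were bound independently and without regard to their number of TSSs, so this rate need not hold for the data. With 30% of 4000 random positions moved to promoters the promoter class was called in all 20 simulations, with 2% moved in 55%, and with none moved in 0%. Of simulated sites kept in all 3 lists, 100% were found again, which was fixed in advance because summits were moved by less than 100 bp. Of the other simulated sites, 0.666% were counted as supported, with extra entries placed at random positions. An 8-mer planted in 3% of 1000 windows was found again in all 20 simulations.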

Results

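Binding of the CG12071 protein was profiled by chromatin immunoprecipitation followed by sequencing (ChIP-seq) in whole embryos of Drosophila melanogaster collected between 12 and 24 hours of age, males and females together. The flies carried a transgene that fuses green fluorescent protein (GFP) to the C-terminal end of CG12071. Chromatin was sheared by sonication to fragments of 200 to 800 bp. The series holds 3 biological replicates of 1 group, so the questions it can answer are where the tagged protein was found and how far the replicates agree, and no comparison between conditions was possible. The description line of each replicate speaks of an input control, whereas the assay, antibody and control fields of the same replicates, and the sample file records, describe an immunoprecipitation called against a separate control. The replicates were treated as immunoprecipitations throughout.

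Each replicate had a list of 30000 entries, peaks and background together, and so did the pooled alignments. The authors' threshold on irreproducible discovery rate left 4261 peaks, here called thresholded peaks, and all of them were found among the 4261 strongest entries of the pooled list. Read depth was unknown, and intervals on shares below cover counting error only. The lists differed in strength: 13828 entries of replicate 1 and 12616 of replicate 2 had a q-value of 0.05 or less, against 4015 of replicate 3, fewer than the number of thresholded peaks.

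The gene that was tagged, CG12071 (FBgn0039808), lies on 3R from 30877084 to 30881027 on the minus strand (dm6). No thresholded summit fell within the gene or 2 kb to either side, and the closest one to a transcription start site (TSS) of the gene was 6202 bp away. The strongest pooled entry of the region, 30880110 to 30880479, had its summit at 30880295 in the first intron of CG12071. It ranked 4346 in the pooled list, after all 4261 thresholded peaks, and 7591, 2990 and 7227 in replicates 1, 2 and 3.

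**Figure D1:**
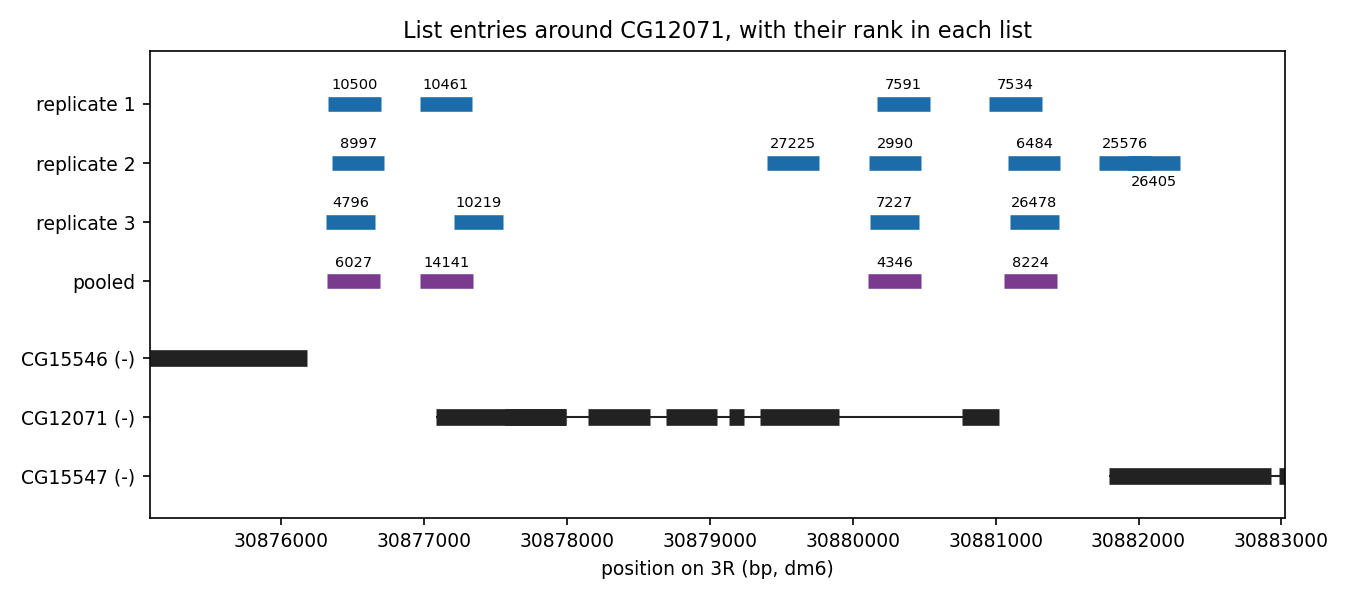
Entries of the replicate lists and the pooled list around CG12071, drawn to scale by position on 3R (x axis, bp), with each entry's rank in its own list above or below its bar and the exons of the annotated genes as black boxes at the bottom. The entry in the first intron ranked 4346 in the pooled list, and no entry shown is a thresholded peak.

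Of the 4261 thresholded peaks, 2066 had a summit within 100 bp among the 4261 strongest entries of every replicate (48.5%, Wilson 95% interval 47.0 to 50%). Peaks moved along their chromosome arms reached at most 0.422% in 100 shifts. The thresholded peaks had been selected for reproducibility from the same 3 replicates, so a share above that of shifted peaks was fixed in advance and no test is given. Support was 76.8% in replicate 1, 80.0% in replicate 2 and 69.7% in replicate 3, and 76 peaks had none. Among the 2130 strongest thresholded peaks, 82.5% were supported in all 3 replicates. Across the thresholded peaks with an entry within 100 bp in both replicates of a pair, Spearman's rho of the signal values was 0.696 between replicates 1 and 2 (4012 peaks), 0.594 between 1 and 3 (3527 peaks) and 0.663 between 2 and 3 (3536 peaks). Peaks without such entries were left out. These values are across peaks, which are not independent replicates.

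Binding was concentrated at promoters and rare in coding sequence. Summits within 500 bp of a TSS of a protein-coding gene made up 40.7% of thresholded peaks (1733 peaks, Wilson 95% interval 39.2 to 42.2%), against 11.5% of random positions drawn on the same arms. Coding exons held 0.399% of summits against 13.9% of random positions, 3' UTRs 1.10% against 4.47%, and intergenic sequence 13.8% against 28.0%. Exons outside these classes, which include those of noncoding genes, held 2.23% against 1.59%. Each of these 5 differences had the smallest p that 1000 random sets allow (permutation p = 0.001, 0.0014 after adjustment over 7 classes). Introns held 40.9% of summits against 39.8% of random positions (adjusted permutation p = 0.170), and 5' UTRs 0.868% against 0.787% (adjusted permutation p = 0.623). The higher share in the other exons was not past the threshold among the 2130 strongest peaks (ratio to random 1.21; adjusted permutation p 0.0012 to 0.227 over its alternatives). With a promoter window of 250 bp introns passed the threshold, at a ratio to random of 1.11 (adjusted permutation p 0.0012 to 0.19 over the alternatives).

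The promoter share was lowest in replicate 3. Among the 4261 strongest entries it was 47.3% in replicate 1, 42.1% in replicate 2 and 31.2% in replicate 3 (mean 40.2% ± 8.19, SD, n = 3), all above the highest share of the random sets, 13.3%. Among the 1000 strongest entries, a limit chosen after the data were seen, the shares were 50%, 48% and 43.9% (mean 47.3% ± 3.11, SD, n = 3). In the thresholded list the strongest quintile of peaks had 48% at promoters and the weakest 40.4%, a difference of 7.56 percentage points (95% interval 2.84 to 12.2). The quintiles between them had 38.7%, 39.6% and 36.6%, so the share did not fall steadily with strength. Thresholded peaks supported in all 3 replicates had 37.3% at promoters, below the 40.7% of all thresholded peaks. Spearman's rho between quintile number and promoter share was -0.30 in the thresholded list and -0.87, -0.70 and -0.90 in replicates 1, 2 and 3, given as values over 5 quintiles without a test.

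**Figure D2:**
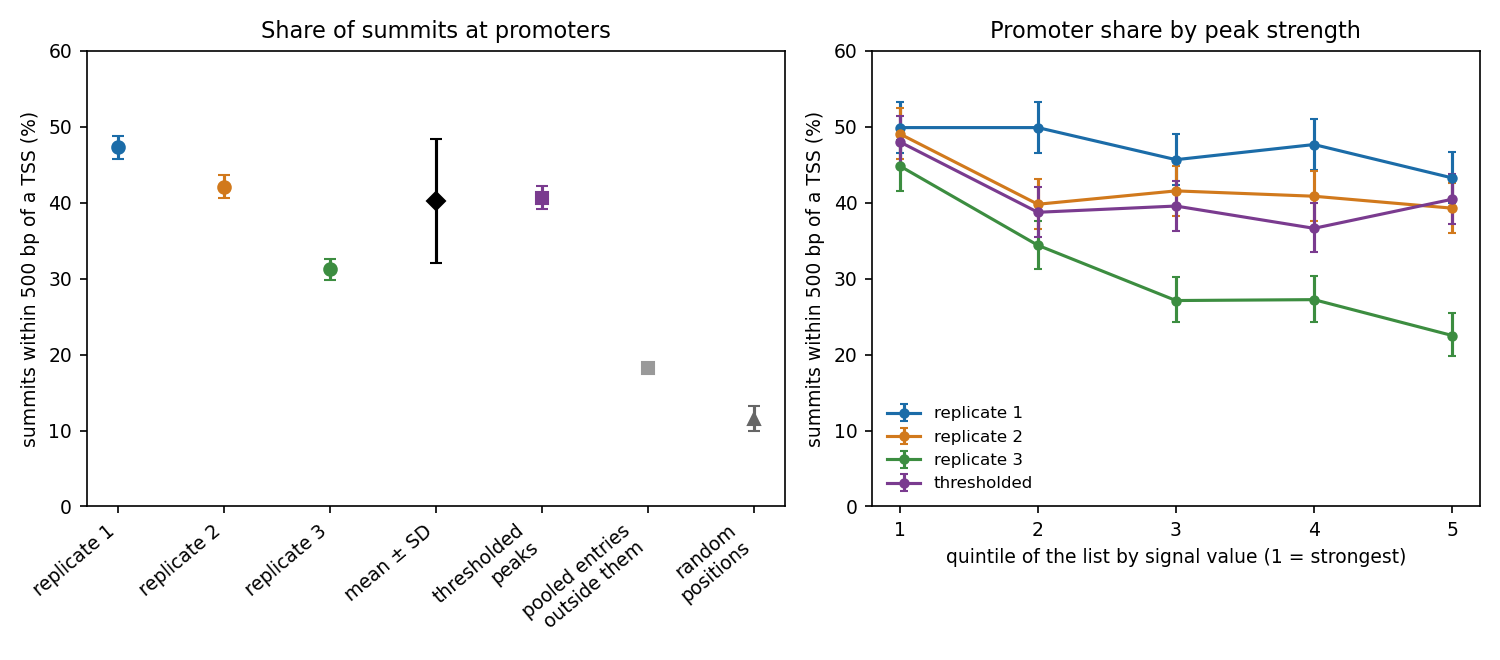
Left, percent of summits within 500 bp of a TSS (y axis) in the 4261 strongest entries of each replicate, their mean with SD (n = 3), the thresholded peaks, the pooled entries outside them and random positions; bars are Wilson 95% intervals, or the lowest and highest of 1000 random sets. Right, the same percent by quintile of signal value (x axis, 1 the strongest) with Wilson 95% intervals. Replicate 3 goes from 44.8% in its strongest quintile to 22.5% in its weakest, and replicate 1 from 49.9% to 43.3%.

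The strongest peak of every list lay at the promoter of Ugalt, the UDP-galactose transporter gene, with its summit 23 bp from a TSS (X, 2703703 to 2704067). It ranked 1 in all 3 replicates, with an authors' signal value of 4816 in the pooled list. The next promoter peaks were at CG14100 (3L, 19590440 to 19590785), at CenG1A, which encodes an Arf GTPase-activating protein (2L, 13835308 to 13835637), at PNPase, the polynucleotide phosphorylase gene (3R, 31404496 to 31404822), and at the wing vein gene px (2R, 22514132 to 22514482). Their mean ranks over replicates were 3.0 ± 1.73, 3.33 ± 1.53, 8.0 ± 1.0 and 9.0 ± 2.65 (SD, n = 3). The Polycomb group gene ph-p ranked 9.67 ± 1.53 with a summit 483 bp from its TSS, and Chro, which encodes a protein of chromosome interbands, 20.3 ± 6.35 (SD, n = 3). The other promoter peaks among the 15 strongest were at CG1888, the arginine methyltransferase gene Art3, CG11309, the glycolytic gene Gapdh2, CG18549, the Hsp90 gene Hsp83, tank and the transcription factor gene Atf3. Of these, Hsp83 differed most in rank, from 14 in replicate 2 to 99 in replicate 3.

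Several of the strongest sites were far from any protein-coding TSS. The strongest such peak lay in an intron of CG11050 (2L, 6612421 to 6612961), 1039 bp from a TSS of that gene, and ranked 3.33 ± 0.577 (SD, n = 3). The next was in an intron of ush (2L, 480909 to 481282), which encodes a cofactor of GATA factors, with the TSS of the zinc-finger gene cbt closest at 1413 bp. It ranked 5.0 ± 1.0 (SD, n = 3). Others lay in an exon of lncRNA:CR31840 (2L, 14023907 to 14024370), in an intron of the kinase gene Lk6 (3R, 11760875 to 11761245), and in intergenic sequence 3148 bp from the TSS of tara (3R, 16222315 to 16222681). Their mean ranks were 8.0 ± 1.0, 14 ± 3.0 and 16.7 ± 4.04 (SD, n = 3).

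Genes for cytoplasmic ribosomal proteins carried the peaks far more often than other genes. Of 13945 protein-coding genes, 1869 (13.4%) had a thresholded summit within 500 bp of a TSS and are called bound here. Of the 92 ribosomal protein genes, 64 were bound (69.6%, Wilson 95% interval 59.5 to 78.0%), against 1805 of 13853 other genes (odds ratio 15.3, two-sided Fisher exact test, adjusted p = 9.7e-34 over 26 lists). In the strongest entries of single replicates the bound share was 76.1%, 75% and 53.3% (mean 68.1% ± 12.9, SD, n = 3), and 49 genes were bound in all 3. Among those with a peak supported in all 3 replicates, the strongest were RpS27 (3R, 25247350 to 25247675), with a mean rank of 45.0 ± 14.2, RpS4 with 98.0 ± 44.7, RpL31 with 169 ± 110 and RpL14 with 170 ± 110 (SD, n = 3). No random list matched on the number of TSSs per gene reached this share, and their median was 17.4%. The other translation lists among the 26 did not pass the test. Bound were 10 of 73 mitochondrial ribosomal protein genes (adjusted exact p = 0.899) and 9 of 44 translation initiation factor genes (adjusted exact p = 0.426).

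Genes of fat body and metabolism were bound in 13 of 29 cases (44.8%, odds ratio 5.28, Fisher exact test, adjusted p = 0.00023; 44.8% ± 3.45 in the replicates, SD, n = 3). The share among other genes was 13.3%, and the median of random lists matched on the number of TSSs was 24.1%; against these lists the call ended (permutation p = 0.017, 0.073 after adjustment over the lists). Those with the strongest peaks act in glycolysis: Gapdh2 with a mean rank of 21 ± 6.24, the hexokinase gene Hex-A with 262 ± 69.0, the enolase gene Eno with 437 ± 173 and the lactate dehydrogenase gene Ldh with 550 ± 275 (SD, n = 3). Pgk and Tpi were also bound, so that 6 of the 10 glycolytic enzyme genes in the list were. So were ACC and FASN1 of fatty acid synthesis and the nuclear receptor genes Hnf4 and svp. The peaks of Tpi (pooled rank 4195, 471 bp from a TSS) and ACC (pooled rank 3555) were not supported in all 3 replicates. None of the 6 larval serum and fat body protein genes (Lsp1alpha, Lsp1beta, Lsp1gamma, Lsp2, Fbp1 and Fbp2) was bound. This division of the list was chosen after its values were seen and was not tested.

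Regulators of chromatin, signalling and the ecdysone response were also bound more often than other genes. Of 53 chromatin and insulator genes 15 were bound (28.3%, odds ratio 2.56, Fisher exact test, adjusted p = 0.012), among them ph-p, Chro, Dref and Cp190. The Dref peak had its summit 4 bp from a TSS of RpL13, a ribosomal protein gene beside it, and the Cp190 peak was closest to CG4338. Of 62 signalling pathway genes 18 were bound (29.0%, odds ratio 2.66, Fisher exact test, adjusted p = 0.0056), led by Stat92E, the transcription factor gene of the JAK-STAT pathway, which ranked 175 in the pooled list and at worst 326 in a replicate. It was followed by the Dpp pathway gene shn with a mean rank of 595 ± 744, the EGF receptor ligand gene spi with 386 ± 179 and Thor, the eIF4E-binding protein gene, with 1480 ± 859 (SD, n = 3). Of 29 ecdysone response genes 10 were bound (34.5%, odds ratio 3.41, Fisher exact test, adjusted p = 0.012), with Eip75B, Kr-h1 and hry at mean ranks of 597 ± 263, 2550 ± 308 and 2769 ± 764 (SD, n = 3). Random lists matched on the number of TSSs had median shares of 15.1% for chromatin, 17.7% for signalling and 24.1% for ecdysone response (permutation p = 0.024, 0.039 and 0.27; 0.088, 0.13 and 0.51 after adjustment over the lists), so that all 3 calls ended against them. The signalling and ecdysone calls also ended with 1 TSS per gene and among peaks supported in all 3 replicates, and all 3 calls ended among the 2130 strongest peaks. Leaving out a replicate kept only thresholded peaks supported by both others. Fewer genes were then bound, so a lost call need not rest on that replicate. Without replicate 1 the exact adjusted p was 0.0997 for signalling and 0.871 for ecdysone response. Without replicate 2 it was 0.055 for chromatin, 0.158 for signalling and 0.842 for ecdysone response. Without replicate 3 it was 0.242 for chromatin. Over all alternatives it ranged from 0.0047 to 0.242 for chromatin, from 0.00043 to 0.188 for signalling and from 0.0050 to 0.871 for ecdysone response (exact tests).

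Lists of 4 kinds were bound less often than other genes. Chemoreceptor genes were bound in 1 of 179 cases (0.559%, odds ratio 0.036, Fisher exact test, adjusted p = 3.7e-09) and cuticle protein genes in 2 of 122 (1.64%, odds ratio 0.11, Fisher exact test, adjusted p = 5.9e-05). The genes concerned, Ir60e, Cpr65Av and Cpr73D, are named because they are so few, after their values were seen. Of 48 proteasome subunit genes none was bound (Wilson upper limit 7.41%, Fisher exact test, adjusted p = 0.0090), and in single replicates 6.25%, 2.08% and 0% were. Of 87 respiratory chain genes 4 were bound (4.60%, odds ratio 0.31, Fisher exact test, adjusted p = 0.032): ND-ASHI, ND-51, ATPsynC and ND-MWFE. ND-ASHI had a mean rank of 129 ± 21.9 and ND-51 of 2464 ± 620 (SD, n = 3), and the ND-ASHI peak lay closer to a TSS of Fum1. The respiratory chain call held in 3 of 14 alternatives (exact adjusted p 0.0193 to 0.668). It was lost without replicate 1, 2 or 3 (exact adjusted p 0.619, 0.264 and 0.185). The settings without a replicate kept fewer peaks, so calls lost there do not show dependence on that replicate. The proteasome call was lost without replicate 1 and without replicate 2 (exact adjusted p 0.178 and 0.158; 0.00123 to 0.274 over the alternatives), although no proteasome gene was bound in either, nor in any other alternative on the thresholded peaks.

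The remaining 17 lists did not pass the test. Among markers of embryonic tissues, 9 of 51 neuronal, 4 of 19 glial, 7 of 43 muscle, 3 of 22 hemocyte, 6 of 29 gut, 4 of 24 tracheal and 5 of 26 epidermal and septate junction genes were bound. These shares, from 13.6% for hemocyte to 21.1% for glial genes, were not below the 13.4% of all genes. Random lists matched on the number of TSSs had higher medians for neuronal (23.5%), muscle (23.3%) and hemocyte genes (18.2%), a lower one for tracheal genes (12.5%) and the same shares for glial, gut and epidermal genes. Lists of this size left wide intervals (glial 8.51 to 43.3%, gut 9.85 to 38.4%, Wilson 95%). None of the 8 Hox genes was bound, a number too small to differ from other genes (exact adjusted p = 0.753). Bound counts were 8 of 33 for heat shock and chaperone genes, 4 of 17 for tubulin and actin genes, 4 of 53 for cell cycle and DNA replication genes, 4 of 40 for mRNA splicing genes, 1 of 20 for germline genes, 1 of 17 for chorion and vitelline membrane genes and 1 of 15 for the E(spl) complex and Bearded family. Of these, heat shock and chaperone genes came closest to the threshold (exact adjusted p = 0.193).

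**Figure D3:**
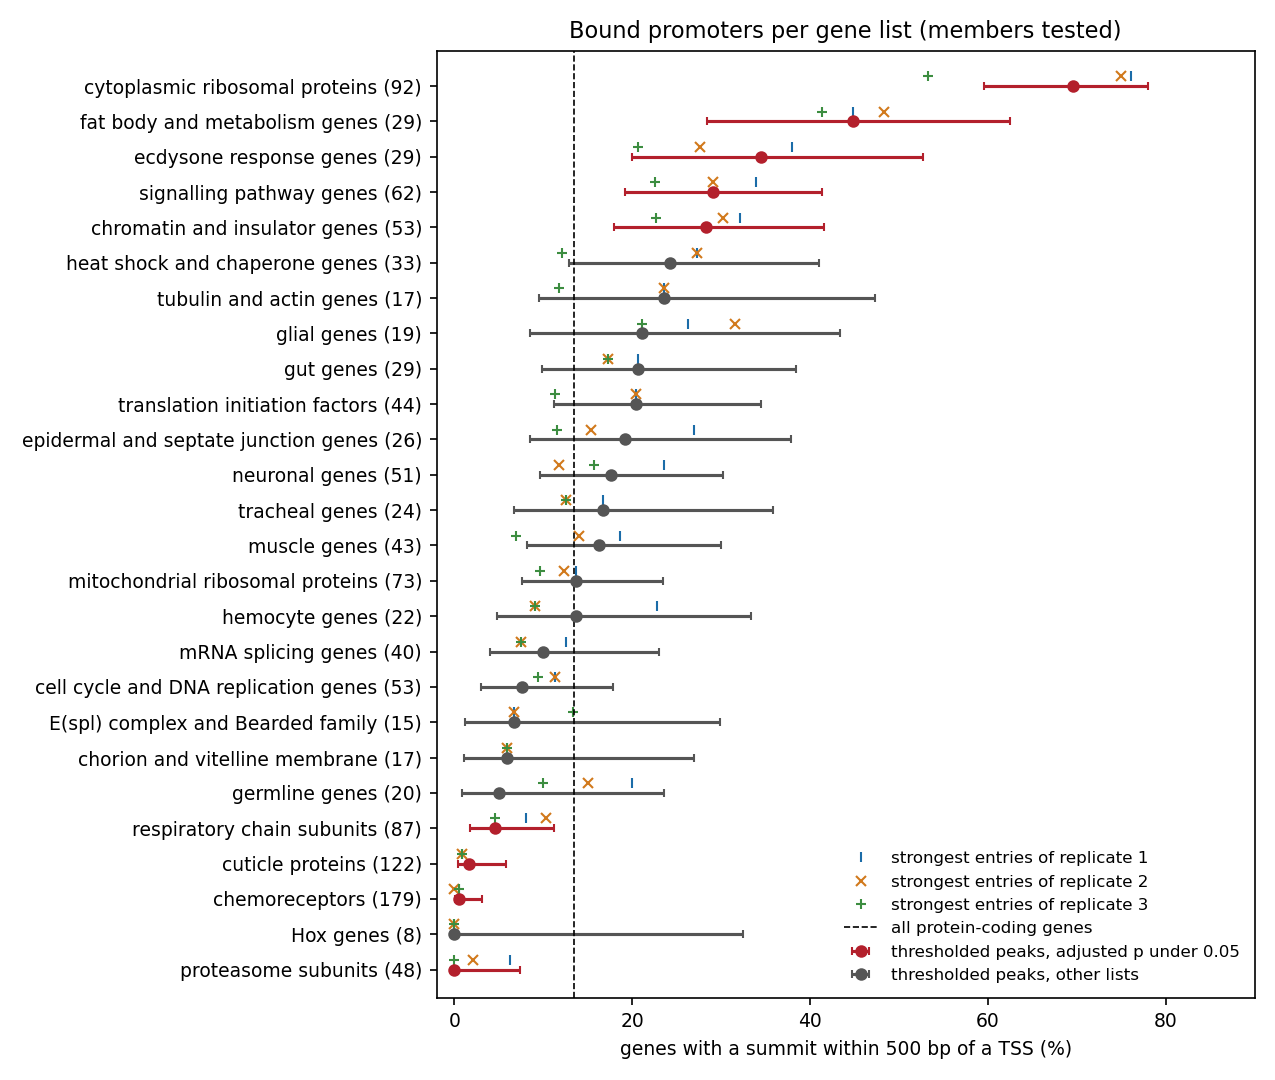
Percent of genes with a summit within 500 bp of a TSS (x axis) for each of the 26 gene lists (y axis, number of genes tested in parentheses). Circles are thresholded peaks with Wilson 95% intervals, red where the adjusted exact p was under 0.05; small marks are the 4261 strongest entries of each replicate, and the dashed line is the 13.4% of all protein-coding genes. Cytoplasmic ribosomal proteins stand highest at 69.6%.

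The bound share of genes with an oppositely oriented neighbour depended on how peaks near both genes were counted. Of 3815 genes with a TSS of another gene on the opposite strand within 500 bp upstream, 695 were bound (18.2%, Wilson 95% interval 17.0 to 19.5%), against 1174 of 10130 other genes (11.6%, 11 to 12.2%; odds ratio 1.70, Fisher exact test, p = 2.1e-23). When each peak was given only to the gene with the nearest TSS, an alternative chosen after the data were seen, the bound counts were 418 of 3815 (11%) and 1119 of 10130 (odds ratio 0.99, Fisher exact test, p = 0.90). The first count lets a peak at either promoter mark both genes and the other takes it from one of them, so neither shows whether divergent promoters were bound more often.

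Chromosome 4 held 4 thresholded peaks, 0.0939% of all, where its share of bases is 0.996% (exact binomial test, adjusted p = 6.8e-13). No arm had more peaks than its bases give after adjustment. At an unadjusted exact p under 0.05, 2L did, with 18.8% of peaks against 17.6% (ratio 1.07, exact p = 0.044, adjusted p = 0.13).

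Of 15 preset motifs, 3 were more frequent within 50 bp of the summit than in the flanks of the same peaks. These were core promoter motif 1 (GGTCACAC, 0.821% of peaks against 0.258%, exact McNemar test, adjusted p = 0.0028), TATA (TATAAA, 14.2% against 11.6%, exact adjusted p = 0.0028) and the BEAF core (CGATA, 13.9% against 11.9%, exact adjusted p = 0.020). A CA repeat (CACACACA, 2.84% against 4.62%, exact adjusted p = 0.00028) and the Grainyhead site (AACCGGTT, 0.0469% against 0.282%, exact adjusted p = 0.039) were less frequent. None of the 5 calls held within 25 bp, and TATA alone held in the other 3 alternatives. Summits had a GC content of 39.5% against 41.8% in flanks. Whether the higher share of TATAAA, made of A and T only, exceeds what this difference gives was not tested. Against random positions matched on arm and promoter status the CA repeat was the more frequent at summits, without passing the test (ratio 1.41; exact adjusted p 5.9e-05 to 0.223 over its alternatives). The DRE element, GAGA, both E-boxes, the Zelda, Mef2, STAT, Pho and GATA sites and the AT-rich homeodomain site did not pass the test. GAGA was at 3.14% in both summits and flanks, and its result depended on the comparison: it was higher at summits against matched random positions (ratio 2.27) and within 100 bp (ratio 1.25), and lower than in flanks among the 2130 strongest peaks (ratio 0.609; exact adjusted p 7.4e-07 to 0.90 over its alternatives). DRE passed within 100 bp (ratio 1.80; exact adjusted p 0.0076 to 0.975 over its alternatives).

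The 10 strongest 8-mers of the 1719 peaks on 2L and 3L were tested in the 2538 peaks on 2R, 3R and X, and 8 were again more frequent at summits than in flanks after adjustment. The clearest was AATATTTG, in 3.90% of summits against 1.10% of flanks (Wilson 95% interval 3.21 to 4.73%, exact McNemar test, adjusted p = 1.2e-09). It shares most of its bases, on one strand or the other, with ACAAATAT (3.43% against 0.985%), AACAAATA (3.55% against 1.26%) and ATATTTGC (3.27% against 1.18%). How often they lay at the same site was not counted. TGTAAACA was in 2.68% against 1.10% (exact adjusted p = 9.0e-05) and GTAAACAA in 2.92% against 1.38% (exact adjusted p = 0.0003). GCAAACAA and AAACAAAT also passed, each with an exact adjusted p of 0.0011, and TAAACAAA (3.59% against 2.60%, exact adjusted p = 0.056) and AAACAAAC (2.96% against 2.64%, exact adjusted p = 0.55) did not.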

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

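The tests in this paragraph were chosen only after the main results had been seen. A signal appeared in entries outside the thresholded peaks, for which no comparison of their own was planned. The pooled list holds 25227 entries that overlap no thresholded peak, and 18.2% of them had a summit within 500 bp of a TSS, against 11.5% of random positions and 12.2% in the highest of 1000 random sets (permutation p = 0.001, the smallest these sets allow). This share lies below the 40.7% of thresholded peaks. Of the 28 ribosomal protein genes without a thresholded peak, 9 had such an entry at a TSS (32.1%), as did 3238 of the 12048 other genes without a thresholded peak (26.9%), a difference that was not detectable (Fisher exact test, two-sided, p = 0.53).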

How the results depend on the processing

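Gene lists in single replicates, the 1000 strongest entries, the promoter share without each replicate, calls from matched draws and divergent promoters by nearest TSS were tests chosen after the data had been seen. No paired analysis was possible because there is 1 group. Of 75 alternative values for summary results, 54 kept their call or stayed within the replicate spread; 7 of these concern replicate support (34.8 to 82.5%), whose test could not have failed. Of 450 values for single lists, motifs, classes and arms, 393 kept their side of the threshold, 50 lost it, 6 gained it and 1 turned direction. Promoter share stayed above its background in every alternative run (30 to 51.2%), and the calls for ribosomal proteins, cuticle proteins and chemoreceptors held in all 14 alternatives each; fat body and metabolism was lost in 1, the matched draws with adjustment. The odds ratio for divergent promoters went from 1.70 to 0.991 when each peak was given to the nearest TSS only, which takes shared peaks from one gene of a pair. Lists with a higher share numbered 5 in the main result, 3 with 1 TSS per gene, 2 among the 2130 strongest peaks, 3 among peaks supported in all 3 replicates, 1 (ribosomal proteins) in matched draws with adjustment, and 2 to 4 when a replicate was left out, with 2 for replicate 2. Lists with a lower share numbered 4, and 2 among the strongest peaks, 2 among supported peaks, 2 in replicate 1 alone, and 2 to 3 when a replicate was left out. Higher preset motifs numbered 3, but 0 within 25 bp, 5 within 100 bp and 1 among the strongest peaks. Lower motifs numbered 2, but 0 within 25 bp, 0 within 100 bp and 0 against matched random positions, where the CA repeat turned to a ratio of 1.41. Higher annotation classes fell from 2 to 1 among the strongest peaks, and 1 arm, 3L, was higher against its share of TSSs (ratio 1.12), where none was against bases. Mean rho between replicates was 0.651, and 0.594 to 0.696 when a replicate was left out. The strongest peaks, the supported peaks and leaving out a replicate each test fewer bound genes; the cause was not tested for the other changes. Unknown read depth limits how far replicate 3 can be set beside the others.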

Other observations

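The tests of noncoding genes, of summit positions, of rearranged 8-mers by their lower limits and of all 10 discovered 8-mers in distal peaks were chosen only after the results they bear on had been seen. Genes for tRNAs carried summits more often than chance: 11 of 290 had a thresholded summit within 100 bp, against a mean of 2.58 for random positions (permutation p = 0.001, the smallest 1000 sets allow; adjusted 0.0025). Of 3261 ncRNA genes, a class that includes the long noncoding RNAs, 193 did, against a mean of 135 and a highest random value of 182 (permutation p = 0.001). Pseudogenes were below chance, with 2 of 268 against a mean of 9.43 (adjusted permutation p = 0.032), and snoRNA genes (3 of 269) and snRNA genes (1 of 32) did not pass the test. The random positions were matched on arm only, and 1 summit can count for several clustered genes.

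Summits at ribosomal protein genes sat close to the TSS. Over 63 promoter peaks whose nearest TSS belonged to a ribosomal protein gene, the median distance was 15 bp and 88.9% lay within 50 bp. Over the 1670 peaks nearest to other genes, the median was 116 bp and 26.1% lay within 50 bp (difference in medians -101 bp, permutation p = 5e-05, the smallest 20000 permutations allow). Distances were to the nearest of all annotated TSSs, and this difference was not matched on the number of TSSs per gene. Among the 500 strongest thresholded peaks, the 227 promoter peaks of other genes had a median position of -144 bp, upstream of the TSS, against -11 bp for the 27 of ribosomal protein genes; over all promoter peaks the medians were -79.5 and -8 bp.

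Binding at ribosomal protein promoters was weighed against 3 explanations. One replicate alone is argued against, since the lowest share in a single replicate was 53.3%, against 10.3% of other genes there. Signal at all strongly transcribed genes alike is argued against for the genes tested. Of 34 genes outside the ribosome taken from general knowledge as abundantly transcribed, 38.2% were bound (Wilson upper limit 55.0%), below the lower limit of 59.5% for ribosomal proteins. The 34 genes were not matched to ribosomal protein genes on transcript level, and transcription was not measured here. A signal that rises with transcription could give the same order, so whether part or all of the signal follows transcription stays open. The share of the 34 genes exceeded the 13.3% of other genes (Fisher exact test, adjusted p = 0.00051). It did not pass the threshold against draws matched on TSS number (median 23.5%, permutation p = 0.082). Binding may extend to other genes of translation, since 4 of 8 elongation factor genes were bound (50%, Fisher exact test, p = 0.014; eEF1alpha1, eEF1gamma, eEF2 and eEF5), although this missed the threshold in draws matched on TSS number (permutation p = 0.093) and initiation factors did not pass; no biological explanation was tested, as there is 1 group.

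The lower promoter share of replicate 3 was weighed against 2 technical explanations. The gap to the mean of replicates 1 and 2 was 13.5 percentage points among the 4261 strongest entries. GC content is argued against: after the entries of replicate 3 were weighted to the GC distribution of the others, the gap was 13.2 points (bootstrap 95% interval 11.7 to 14.6). Weak entries in the lower ranks remain a candidate explanation, since the gap was 5.1 points among the 1000 strongest entries (95% interval 1.32 to 8.88). The lower share was not confined to entries past a q-value of 0.05, since 4015 entries of replicate 3 were within it. In the middle quintile of the 4261 strongest entries, replicate 3 already had 27.1% at promoters, against 45.7% and 41.5% in replicates 1 and 2. Among the 2130 strongest entries the shares were 49.2%, 42.6% and 37.4% in replicates 1, 2 and 3. The interval at 1000 entries leaves room for a further difference, and no biological explanation was tested.

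The 8-mers at summits were weighed against base composition and promoter elements. Promoter elements alone are argued against, since 19.9% of 1518 distal peaks on the test arms held any of the 8 sequences against 8.17% of their flanks, though these sequences had been kept for their frequency on the same arms, and 23.1% held any of the 10 sequences discovered on the other arms against 11.5% (exact McNemar test, p = 1.1e-17). Neither prediction set beforehand for base composition was met. The 8 sequences had a median percentile of 95.3 among 8-mers of the same letters, above the limit set for composition as the cause. They had been kept for their frequency on the same arms, so a high median was partly fixed in advance and decides nothing. TAAACAAA and AAACAAAC, discovered but not kept, were at percentiles 75.9 and 69.6. Of the 8 sequences, 3 were below the 95 that each had to reach to argue against composition. These were TGTAAACA (92.0, the lowest), GTAAACAA (92.4) and GCAAACAA (93.2). A later test argues against single-letter composition as the whole cause, since for 8 of the 10 discovered sequences the lower 95% limit of the ratio of summit-only to flank-only peaks lay above the median and the total of the same ratio over rearranged sequences. These were the same 8 that had passed against flanks on these arms. Several share most of their bases, so they are not 8 separate pieces of evidence. The composition of neighbouring bases was not tested and stays open; TGTAAACA holds the core recognised by forkhead-domain proteins, and no biological explanation was tested.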
